A study of Mus musculus with 6 samples.

How the data were processed

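Colon tissue of 6 wild-type male mice was profiled by RNA-seq, with 1 library per mouse: 3 resting mice (15, 17 and 19) and 3 mice taken right after the third of 3 episodes of 30-min restraint (10, 11 and 13). Restraint is a standard way to stress a rodent, in which the animal is held in a tight enclosure. The records of the resting mice carry the same note on restraint as those of the stressed mice, so the groups rest on the treatment label; whether resting mice were handled or kept from food in the same way is not given in the sources used here, and the comparison may include such differences. Per the labels' protocols, RNA was extracted with a column kit, checked for integrity and turned into stranded libraries after poly(A) selection. Poly(A) selection keeps messenger RNA and loses most ribosomal and small RNA. The deposited table holds raw read counts, as whole numbers per Ensembl gene, for 43432 gene identifiers in the 6 libraries. The submitters' processing notes name fastp, HISAT2 and the mm10 build of the mouse genome, with no version or setting. The read counter, the gene annotation and the strand setting of the counting are not given in the sources used here. Overlapping and antisense genes, and members of gene families with near-identical copies, are therefore uncertain where reads could be split between them.

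Library totals were between 16425525 and 19819267 counts. Gene symbols were taken from a table of Ensembl identifiers and coordinates from GENCODE M21 for the same build; 42462 identifiers had a symbol, and the other 970 held between 0.0988% and 0.105% of the counts of a library. Groups were taken from the sample labels. The labels name a separate mouse for each library, so each counted as a replicate, and no 2 libraries looked like copies of 1 library (chi-square per gene of 7.84 to 18.5). The sex of the animals is read from the counts: the Y-linked gene Ddx3y was at 91.8 ± 6.98 CPM (counts relative to the library total, in the usual scale) in resting and 84.6 ± 3.44 in stressed mice (SD, n = 3 each), and Xist had at most 8 counts in a library.

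Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test on the deposited counts. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 16119, and libraries were scaled by TMM factors between 0.985 and 1.02. Benjamini-Hochberg adjusted p under 0.05 was the threshold, in both directions. Log2 fold changes are stressed over resting, and their standard errors and 95% intervals come from the same fit. CPM values are scaled by the TMM factors. The 44 gene lists were fixed from textbook knowledge before the data were examined, and of their 857 entries 852 were matched to an identifier by symbol and 2 by a synonym. Lists with at least 5 tested members (41 lists) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and adjustment over the lists. Camera asks whether the genes of a list move more to one side than the other genes. For each list, the number of members past the threshold is also given when p-values were adjusted over the list alone.

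The named genes were also fixed by a rule before the data were examined. The first part takes up to 10 genes per direction with the largest change among those past the threshold, with a mean of at least 1 CPM, no overlap between the groups and a symbol other than a predicted-gene name; where fewer met this, the genes with the smallest p filled the 10. The second part takes in each list up to 4 members that pass, or up to 2 with the smallest p where none does. The third part takes 11 stress genes and the sex genes whatever their values. Gm26917 passed the threshold, has a predicted-gene name and was named after its values were seen. A few genes that the rule names are not reported here.

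The test was checked on data simulated for the comparison of stressed with resting mice, with 200 changed genes in each of 5 simulations and 15941 genes tested. Beside these, the other members of the cholesterol synthesis and circadian clock lists were shifted by 0.3 on the log2 scale. Calls of such list genes were not counted as false. With gene-wise dispersions it recovered 53.9% of genes changed 1.5-fold, 77.7% of those changed 2-fold and 97.5% of those changed 4-fold, and 9.0% of calls were false. With trended dispersions the shares were 58.0%, 81.2% and 99.4%, with 3.8% of calls false. The 5 simulations together gave 855 calls with gene-wise dispersions, against 5 changed genes in the data. The adjustment asks for a smaller p where fewer genes pass, so these shares are likely too high for the data. Lists whose genes were shifted by 0.3 on the log2 scale were called in 10 of 10 cases, and other lists in 1 of 195 and 1 of 194. The simulated genes varied independently of one another, so these list figures do not cover lists whose genes vary together.

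Alternatives fixed in advance were DESeq2 size factors, upper quartile scaling and library totals in place of TMM, no filter (only genes with no count left out), a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0 (Wald test), limma-voom with and without sample weights, a smooth muscle score or a B and plasma cell score as a covariate, an adjusted p under 0.1, a fold limit of 1.5, and leaving out each mouse in turn. The lists were also tested with a correlation estimated per list and with fry. The fits with a Hoxa score or an adipocyte score as a covariate were chosen after seeing the data. A score is the mean log2 CPM of a list's genes in a library after centring each gene.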

Results

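The colon transcriptome was compared between wild-type mice at rest and mice whose colon was taken right after the third 30-min restraint episode, with 3 mice per group and 1 poly(A) RNA library per mouse. The resting libraries held 16425525, 16735416 and 18209033 counts and the stressed libraries 19819267, 18584545 and 16575181. Mitochondrially encoded transcripts took 6.65% to 7.29% of the counts, with overlapping ranges in the 2 groups. The correlation of log2 CPM between libraries was 0.987 to 0.9893 within a group and 0.9854 to 0.9887 between groups. The first principal component held 24.9% of the variance and the second 21.6%. On the first, resting mice 15, 17 and 19 lay at -16.4, -24.0 and 1.95, and stressed mice 10, 11 and 13 at 5.96, 8.5 and 24.0. Resting mouse 19 thus lay nearer to stressed mouse 10 than to the other resting mice.

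Stressed colon had more S100g RNA in all 3 mice. S100g, which encodes the vitamin D-dependent calcium-binding protein calbindin-D9k, stood at 306 ± 82.0 CPM in stressed and 88.8 ± 8.22 CPM in resting mice (SD, n = 3 each), a log2 fold change of 1.78 ± 0.17 (SE) and a 3.44-fold rise (edgeR, adjusted p = 0.00858). Me1, the cytosolic malic enzyme that supplies NADPH for fatty acid synthesis, rose from 36.2 ± 0.0992 to 54.5 ± 3.95 CPM (log2 fold change 0.59 ± 0.07, adjusted p = 0.0296). H2-Q1, a class Ib major histocompatibility gene, rose from 60.4 ± 2.57 to 91.1 ± 4.42 CPM (log2 fold change 0.59 ± 0.07, adjusted p = 0.0246). Igkv6-14, an immunoglobulin kappa variable segment, rose from 0.213 ± 0.0702 to 3.73 ± 1.86 CPM (log2 fold change 4.10 ± 0.50, adjusted p = 0.0246). Gm26917, a predicted long noncoding RNA, fell by 2.07 ± 0.21 on the log2 scale, from 84.0 ± 27.9 CPM, with all 3 stressed mice between 18.7 and 21.4 CPM (adjusted p = 0.00858). It was singled out after its values were seen.

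These 5 genes, 4 higher and 1 lower, were the changed genes among 16119 tested by edgeR's quasi-likelihood test. In mm10, S100g (ENSMUSG00000040808) lies on chromosome X from 162961992 to 162964599, Me1 (ENSMUSG00000032418) on chromosome 9 from 86581371 to 86695953, H2-Q1 (ENSMUSG00000079507) on chromosome 17 from 35320405 to 35325099 and Igkv6-14 (ENSMUSG00000096844) on chromosome 6 from 70434952 to 70435476. Gm26917 (ENSMUSG00000097971) lies on chromosome 17 from 39843013 to 39846341, in a region that holds a copy of the ribosomal RNA genes. Whether its reads come from ribosomal RNA was not tested. H2-Q1 and Igkv6-14 belong to families of similar genes that reads may not tell apart. All 7 tested H2-Q genes had log2 fold changes above 0, with a median of 0.31, and 1 of them passed. The 102 tested immunoglobulin variable segments ranged from -3.77 to 4.10 on the log2 scale, with an SD of 1.27. The 3 resting values of Me1 lie closer together (SD 0.0992 CPM) than counting error alone gives (1.45 CPM). Over all genes, 1116 had an unadjusted p under 0.05 (567 higher and 549 lower, 6.92% of those tested), and the groups did not overlap for 2048 genes, or 12.7%, where chance gives 10%. A split of the mice that mixed the groups gave 1187 genes with an unadjusted edgeR p under 0.05, more than the real groups. Leaving out resting mouse 15 left Gm26917 as the 1 changed gene, and leaving out stressed mouse 10 left S100g; without stressed mouse 11 there were 14. DESeq2 called 56 genes and edgeR without the filter 151, both with all 5 among them. limma-voom called 3 and left out Me1 (adjusted p = 0.06) and Igkv6-14 (0.18). With each mouse left out in turn, Me1 passed the edgeR test only without stressed mouse 11 (adjusted p = 0.0402, otherwise 0.0552 to 0.326). H2-Q1 and Igkv6-14 passed only without stressed mouse 11 or 13. S100g failed only without resting mouse 15 (0.106), and Gm26917 only without stressed mouse 10 (0.0552).

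**Figure D1:**
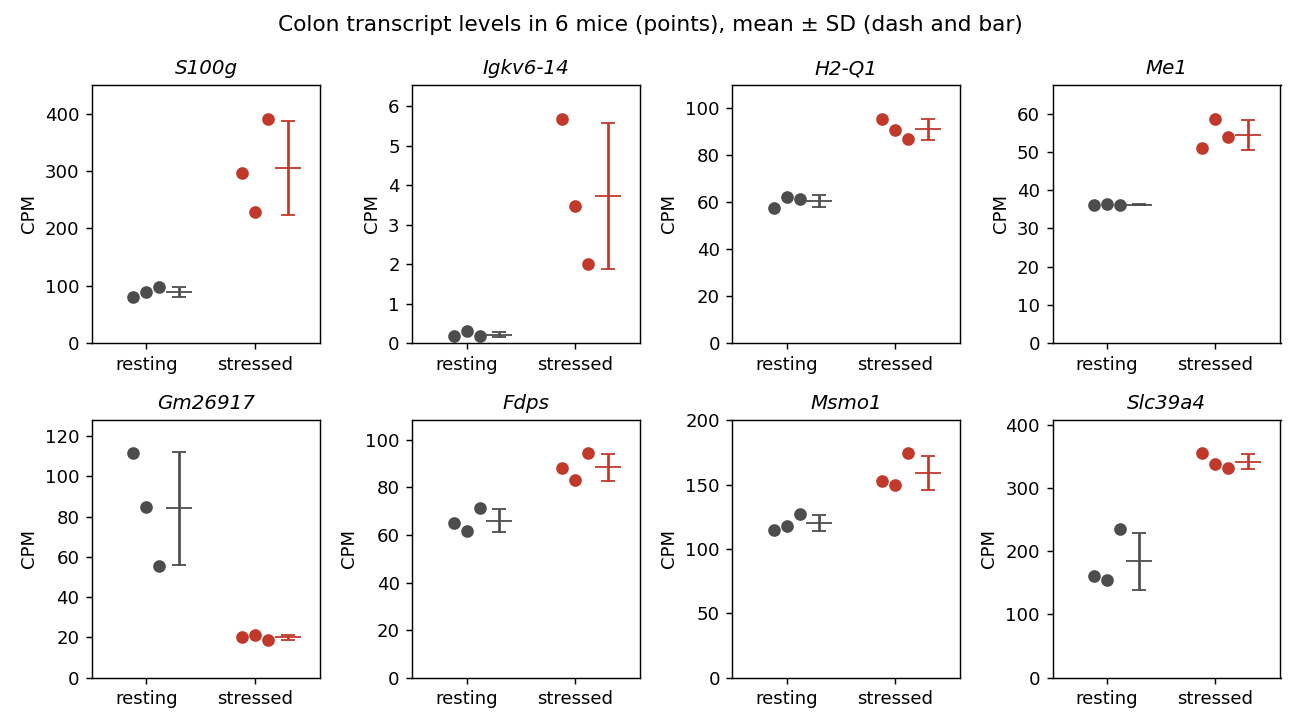
Transcript levels in CPM (vertical axes, from 0) for the 5 changed genes and for Fdps, Msmo1 and Slc39a4, which did not pass over all genes, in 3 resting and 3 stressed mice. Points are mice, dashes are means and bars are SDs (n = 3); in all 8 genes the groups do not overlap, as for S100g at 80.6 to 97.1 CPM in resting mice and at 228 CPM or more in stressed mice.

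Among genes with higher values that did not pass, Slc39a4, the zinc importer ZIP4, was at 342 ± 11.9 against 184 ± 44.5 CPM (log2 fold change 0.89 ± 0.14, edgeR adjusted p = 0.13) and Scd1, the stearoyl-CoA desaturase, at 162 ± 24.0 against 79.6 ± 21.9 CPM (1.03 ± 0.17). Igfbp6 (0.97), Dnase1l2 (0.63), Tlr2 (0.55) and Ifit3 (0.54) completed the higher genes of the naming rule. On the lower side no gene with a full symbol passed. The clock gene Per2 had a log2 fold change of -0.45 ± 0.08 (adjusted p = 0.186), and Atoh1, the transcription factor that specifies secretory cells, -0.57 ± 0.11 (adjusted p = 0.186). The water channel gene Aqp4 had -1.04 ± 0.22. The others on that side were Pacsin1 (-0.71), Abca1 (-0.46), Emsy (-0.42), Hsph1 (-0.41), Fastkd1 (-0.39), Uhrf1bp1l (-0.32) and Flrt3 (-0.31). For each of these 16 genes the groups did not overlap.

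None of the 11 stress genes fixed in advance passed. Fkbp5, a classic glucocorticoid target, was at 326 ± 23.0 CPM in stressed and 301 ± 42.5 CPM in resting mice, with a log2 fold change of 0.11 (95% interval -0.12 to 0.34). The intervals were -0.28 to 0.37 for Tsc22d3, -0.18 to 0.39 for Per1 and -0.61 to 1.07 for Zbtb16, also glucocorticoid targets. Sgk1, the serum and glucocorticoid-regulated kinase, came nearest, at 0.34 (0.04 to 0.64, edgeR adjusted p = 0.654). For the glucocorticoid receptor gene Nr3c1 the interval was -0.13 to 0.21. Of the immediate early genes, Fos had a log2 fold change of 0.22 (-0.33 to 0.78), Egr1 0.46 (-0.20 to 1.13) and Nr4a1 0.06 (-0.49 to 0.60). The inducible heat shock genes Hspa1a (-0.45 to 0.43) and Hspa1b (-0.31 to 0.25) were as close to 0. A doubling lies outside the intervals of all of these except Zbtb16 and Egr1.

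**Figure D2:**
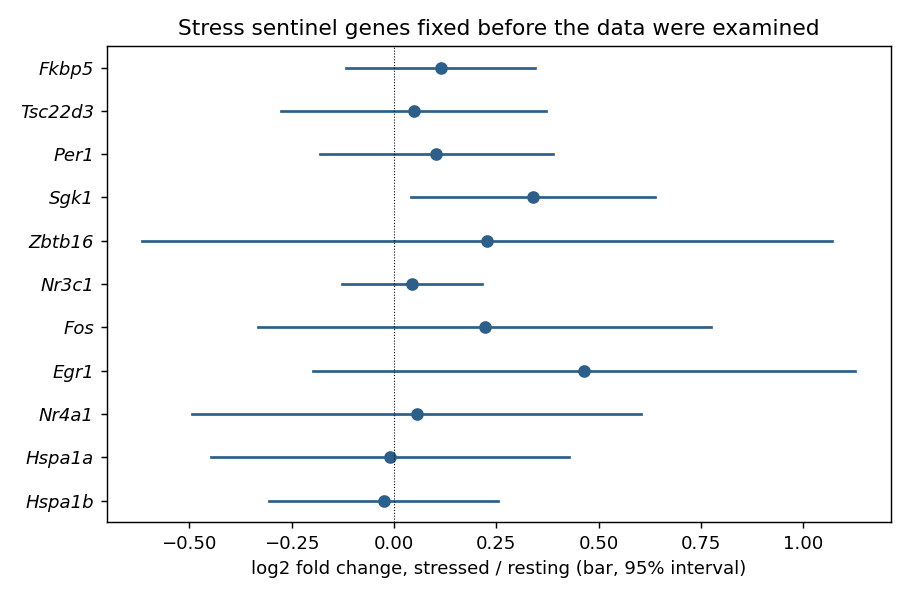
Log2 fold change of stressed over resting mice (horizontal axis) for the 11 stress genes, with 95% intervals as bars (n = 3 mice per group). The interval of Sgk1, 0.04 to 0.64, is the one that lies wholly above 0, and its adjusted p did not pass.

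Lists of genes that respond to stress signals gave no call for glucocorticoid receptor targets or immediate early genes in the main test. Of 30 glucocorticoid receptor targets 21 were higher and 9 lower (median log2 fold change 0.11, camera adjusted p = 0.0664; 0.00992 to 0.906 over the alternatives, 4 of which called it); Nfkbia (0.43) passed when adjusted over the list alone, and Tat had 0.41. Of 27 immediate early genes 16 were higher (median 0.08, adjusted p = 0.795), among them neither Atf3 (-0.36) nor Ccn1 (-0.54). In the list of cAMP and CREB targets (adjusted p = 0.555) Nr4a3 had 1.14 and Per2 -0.45, and Per2 passed when adjusted over the list alone. Heat shock genes and cytosolic chaperones fell as a list, with 16 of 20 lower and a median of -0.07 (adjusted p = 0.0465), led by Hsph1 and by Hspa8 (-0.20). This call was lost with an estimated correlation (adjusted p = 0.722), by fry, with DESeq2 size factors, without the filter, with the smooth muscle, adipocyte or Hoxa score, and without mouse 15, 19, 10 or 13. The unfolded protein response list, with Hyou1 (-0.29) and Hspa5 (-0.24), had 16 of 21 genes lower (adjusted p = 0.0811), and 3 of its genes passed when adjusted over the list alone. Circadian clock genes had 9 higher and 10 lower (adjusted p = 0.193), with 3 lower genes past the threshold over the list alone, Per2 being the first of these. The neuropeptide and stress ligand list (adjusted p = 0.936) had Adrb1 at -0.80 and Vipr1 at -0.23.

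Cholesterol synthesis genes were higher in stressed colon in 20 of 20 cases, with a median log2 fold change of 0.32 (camera adjusted p = 8.72e-13 with the preset correlation). With a correlation estimated for this list (0.682) the call was lost (adjusted p = 0.722, unadjusted 0.0892). No member passed over all genes, and 12 passed when adjusted over the list alone, all higher. Fdps, the farnesyl diphosphate synthase, was at 88.5 ± 5.66 against 66.0 ± 4.80 CPM (log2 fold change 0.42 ± 0.08, edgeR adjusted p = 0.186 over all genes), and Msmo1, a sterol C4-methyl oxidase, at 159 ± 13.3 against 120 ± 6.27 CPM (0.41 ± 0.08). Cyp51 had 0.45 and Hmgcs1 0.39. In the fit with the Hoxa score as a covariate, chosen after seeing the data, 18 of 20 stayed above 0 with a median of 0.13 and none passed over the list alone. Without resting mouse 15 or without stressed mouse 13, 4 members passed over the list alone.

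Other lists called by camera shifted less per gene or held fewer genes. Cell cycle genes rose as a list, with 23 of 25 higher (median 0.25, adjusted p = 1.55e-05, but 0.722 with an estimated correlation); Ccnb1 had 0.52 and Tyms 0.33. Nuclear-encoded oxidative phosphorylation genes had 27 of 28 higher with a median of 0.08 (adjusted p = 0.000617, but 0.802 with an estimated correlation), including Ndufa2 (0.23) and Atp5o (0.21). Interferon response genes had 25 of 32 higher with a median of 0.13 (adjusted p = 0.0072, but 0.722 with an estimated correlation), with Ifit3 at 0.54 and Zbp1 at 0.43, and 8 passed when adjusted over the list alone, 7 of these higher. The interferon call was also lost without resting mouse 15 or 17 or stressed mouse 11 or 13. None of these 3 lists had a member past the threshold over all genes. With the Hoxa score as a covariate the mean log2 difference was -0.0166 for cell cycle and -0.10 for interferon response, the opposite direction.

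Among cell type lists, enteric neuron markers were higher in 19 of 22 cases (median 0.18, adjusted p = 0.000104, but 0.722 with an estimated correlation), with Nefl at 0.70 and Tubb3 at 0.45. Smooth muscle markers were higher in 17 of 20 (median 0.105, adjusted p = 0.00884, but 0.802 with an estimated correlation), with Ldb3 at 0.51 and Hspb7 at 0.27. Stem and transit amplifying markers were lower in 15 of 19 (median -0.06, adjusted p = 0.0426, but 0.722 with an estimated correlation), with Sox9 at -0.42 and Rgmb at -0.16. Mast cell markers were lower in 4 of 5 (median -0.41, adjusted p = 0.0465, but 0.722 with an estimated correlation). Mcpt1, a mucosal mast cell protease, had -2.33 at 0.272 ± 0.331 against 1.43 ± 0.844 CPM, and Gata2 -0.63. Of the 16 mast cell markers listed 5 were tested, and most, such as Cpa3 and Cma1, had too few counts. Kit and Tph1 also stand in the interstitial cell and enteroendocrine lists, so this call says little about mast cells.

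The other epithelial, immune and stromal lists were not called. Of 20 colonocyte markers 11 were higher and 9 lower (adjusted p = 0.936), and 6 passed when adjusted over the list alone, 3 in each direction; carbonic anhydrase gene Car1 had 0.45 and Aqp4 -1.04. Goblet cell markers gave Atoh1 and Spdef (-0.30) past the threshold over the list alone (list adjusted p = 0.648). Enteroendocrine markers had Scgn at 0.41 and Nts at 0.29 (adjusted p = 0.555), and tuft cell markers Pou2f3 at -0.39 and Ptgs1 at -0.38 (adjusted p = 0.936). B and plasma cell markers had Cd79a at -0.77 and Cd79b at -0.67 (adjusted p = 0.146). Macrophage and dendritic cell markers had Flt3 at -0.73 and Cx3cr1 at -0.68 (adjusted p = 0.193), and T cell and innate lymphoid markers Cd2 at -0.999 (adjusted p = 0.535). Cd2 was at 0.865 CPM in stressed and 1.74 CPM in resting mice. Neutrophil and eosinophil lists had too few tested members for a test. Mmp9 had -0.97, at 0.324 against 0.652 CPM in resting mice, Csf3r -0.11, Siglecf -0.43 and Alox15 0.66. Fibroblast (Grem1 -0.77, Pdgfra -0.31), endothelial (Lyve1 0.39, Eng -0.37), enteric glia (S100b 0.52) and interstitial cell of Cajal lists (Etv1 0.20, Gja1 0.09) had adjusted p-values of 0.936, 0.708, 0.344 and 0.347.

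In the antimicrobial and mucosal defence list (adjusted p = 0.737) the defensin gene Defb37 had 1.02 and passed when adjusted over the list alone, and Ang4 had -0.76. Inflammatory cytokines and chemokines (adjusted p = 0.406) had Il1b at 1.47, at 2.11 ± 1.08 against 0.749 ± 0.241 CPM, and Ptgs2 at -0.61. Class II presentation genes had H2-Aa at 0.18 and Ctss at 0.05 (adjusted p = 0.737), and the NF-kB feedback list Nfkbia at 0.43 and Tnip3 at -0.64 (adjusted p = 0.936). H2-Aa was at 64.5, 78.8 and 279 CPM in stressed mice 10, 11 and 13, against 111 to 144 CPM in resting mice. Cd74 and Ciita were also highest in mouse 13. Without that mouse the class II list was called lower, and the lowest mean log2 difference with a mouse left out was -0.51. Tight junction components had Cldn8 at -0.53 and Cldn2 at -0.47 (adjusted p = 0.555). Aldosterone-responsive sodium transport genes had Sgk1 at 0.34 and Hsd11b2, which inactivates corticosterone, at -0.31 (adjusted p = 0.193). Hsd11b2 and Hsd3b2 (-0.26) led the steroid synthesis list, with 4 higher and 4 lower (adjusted p = 0.749). Fatty acid oxidation genes had Slc25a20 at 0.16 and Fabp2 at -0.19 (adjusted p = 0.406).

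Of the lists for neighbouring tissues, those of adipocytes and of small intestine and Paneth cells were called with the preset correlation. Adipocyte markers were higher in 13 of 15 cases (median 0.29, camera adjusted p = 0.000159, but 0.722 with an estimated correlation), with Retn at 0.95 and Plin1 at 0.73. Markers of small intestine and Paneth cells were higher in 7 of 9 (median 0.20, adjusted p = 0.00884, but 0.722 with an estimated correlation), with the sucrase-isomaltase gene Sis at 56.8 ± 22.5 against 28.0 ± 3.57 CPM and Rbp2 at 0.52. These 9 come from 20 listed markers, of which the defensin genes, Apoa4 and Lct, among others, had too few counts to test. All 4 tested haemoglobin list genes were higher, too few for the list test, and all passed when adjusted over the list alone. Hbb-bt had 1.57 and Hba-a2 1.82, both at low levels. Hbb-bt was at 3.01 ± 0.42 against 1.01 ± 0.29 CPM and Hba-a2 at 3.02 ± 0.59 against 0.86 ± 0.64 CPM. In the list of distal colon position markers (adjusted p = 0.936) Hoxa13 had -2.60, at 9.64 ± 7.04 CPM in resting and 1.55 ± 0.851 CPM in stressed mice with overlapping groups, and Insl5 -0.50. Skeletal muscle markers (Acta1 0.88, Ryr1 0.42) had an adjusted p = 0.0912 and pancreatic acinar markers (Sycn -0.42, Cela1 -0.19) 0.113. Mitochondrially encoded mRNAs (mt-Nd6 0.21, mt-Nd1 0.18) and ribosomal protein genes (Rpl13 0.07, Rpl32 -0.07) had adjusted p-values of 0.13 and 0.936.

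In all, 11 of the 41 tested lists were called with the preset correlation, 8 higher and 3 lower, and none held with a correlation estimated per list (smallest adjusted p = 0.722) or by fry in one direction (smallest adjusted p = 0.578). By fry in either direction 1 list passed, steroid synthesis in the intestine. At an unadjusted p under 0.05 the estimated correlation left 1 list and fry 2. The median, the mean and the test differed in sign for the goblet, enteroendocrine, class II presentation, colonocyte and tuft lists and for the neuropeptide list.

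**Figure D3:**
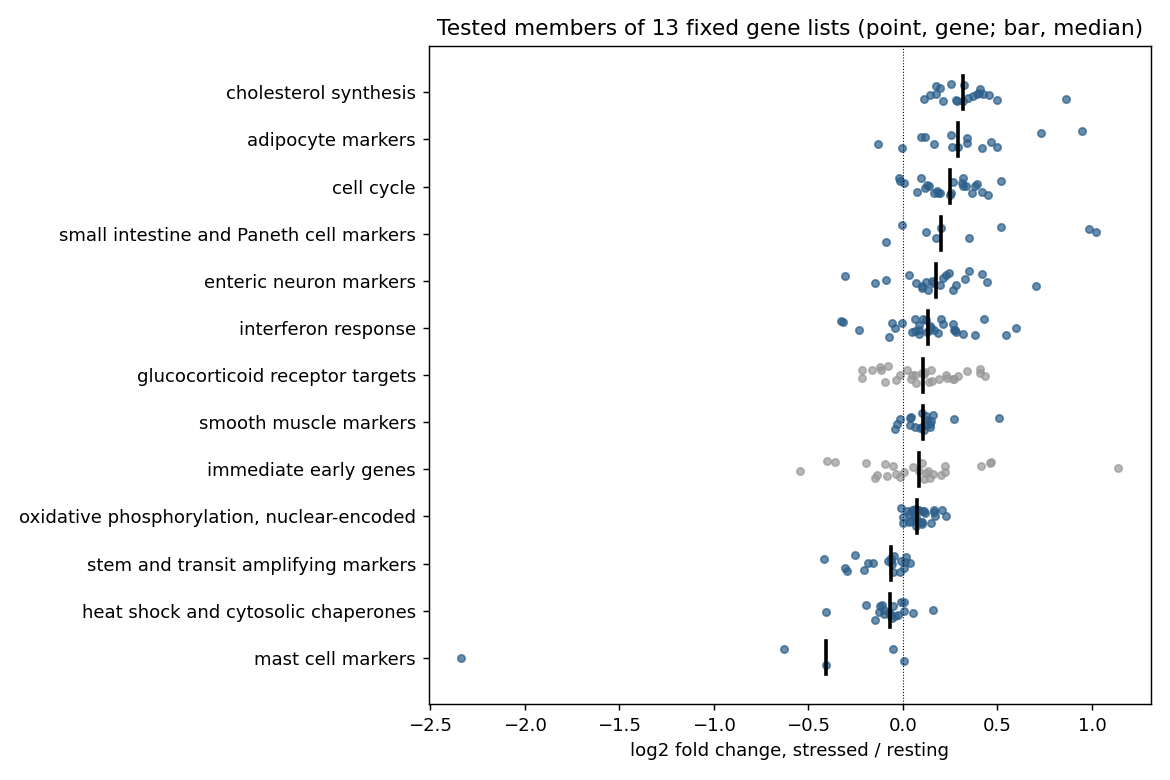
Log2 fold change of stressed over resting mice (horizontal axis) of the tested members of the 11 lists called with the preset correlation (blue) and of 2 lists that were not called, glucocorticoid receptor targets and immediate early genes (grey). Points are genes and bars are list medians, which run from -0.41 for mast cell markers to 0.32 for cholesterol synthesis.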

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

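The fits with the Hoxa or adipocyte score were chosen after seeing the data. Counts of changed genes (5, with 4 higher and 1 lower) stayed within 1.5 times with DESeq2 size factors, upper quartile scaling, library totals, the stricter filter, the B and plasma cell score, an adjusted p under 0.1, the fold limit of 1.5 and the adipocyte score; the cause of the other moves was not tested unless stated. Without the filter edgeR called 151 (106 higher, 45 lower), with 25666 genes tested in place of 16119 and prior degrees of freedom of 41.9 in place of 6.43. The DESeq2 Wald test called 56 (49 and 7). limma-voom called 3 (2 and 1) with and without sample weights. The smooth muscle score gave 8 (6 and 2) and the Hoxa score 3 (2 and 1). A similar count did not mean the same genes: of the 5, the B and plasma cell score kept 3 among its 5, the smooth muscle score 2 among its 8, the adipocyte score 1 among its 6 and the Hoxa score 1 among its 3. Leaving out each mouse in turn gave 1 to 14 changed genes, 0 to 12 higher and 0 to 4 lower: 1 without resting mouse 15 or stressed mouse 10, and 14 without stressed mouse 11. S100g had an adjusted p of 0.106 without resting mouse 15, and its adjusted p ran from 1.71e-16 to 0.122 over the alternatives. Lists numbered 11 in the main test, 0 with an estimated correlation, 0 by fry and 7 with the adipocyte score; leaving out each mouse gave 9 to 14. Of the 11, cholesterol synthesis, cell cycle, enteric neurons and adipocytes stayed called with each mouse left out; the calls were lost for heat shock genes without mouse 15, 19, 10 or 13, interferon response and stem markers without 15, 17, 11 or 13, oxidative phosphorylation without 17 or 11, smooth muscle without 19, 10 or 11, mast cells without 17 or 13, and small intestine without 15 or 11. The Hoxa score ended the calls of all but cholesterol synthesis, smooth muscle, enteric neurons and adipocytes, and the adipocyte score those of heat shock genes, stem markers, smooth muscle, enteric neurons and small intestine. Heat shock genes were also lost with DESeq2 size factors, without the filter and with the smooth muscle score, stem markers without the filter, and mast cells without the filter, with library totals and with the stricter filter. Glucocorticoid receptor targets (adjusted p = 0.0664 in the main test) were called with library totals (0.0328), with the stricter filter (0.0498), without resting mouse 17 (0.0197) and without stressed mouse 13 (0.00992), and had 0.906 with the adipocyte score. Reversed list directions (mean log2 difference) were class II presentation with the adipocyte score (0.55), interferon response (-0.10), cell cycle (-0.0166), tuft cells (0.26) and ribosomal proteins (0.11) with the Hoxa score, and ribosomal proteins without stressed mouse 13 (leaving out each mouse gave -0.0815 to 0.0592). Class II presentation was called lower without stressed mouse 13. In alternatives that keep all mice, 57 named-gene values newly passed and 18, all from the 5 changed genes, no longer passed. All 30 sign changes were in values passing in neither fit. The 1445 that kept direction and side of the threshold mostly passed in neither fit. No paired analysis was possible because the mouse numbers are not shared between the groups. With 3 mice per group, changes of 1.5-fold were recovered in about 53.9% of simulated cases. The simulations held 200 changed genes each beside the shifted list genes, which eases the adjusted threshold, so this share is likely too high for a comparison with 5 changed genes.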

Other observations

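The tests in this part were chosen after the result was seen, as were the mineral absorption, fatty acid synthesis, mesothelial and Hox gene groups; the other lists were fixed before. Of 12 tested genes of mineral absorption and vitamin D response other than S100g, 9 were higher in stressed colon; 6 of these and 2 of the 3 lower ones had an unadjusted edgeR p under 0.05. Slc11a2, the iron and manganese importer, had a log2 fold change of 0.71 ± 0.14 (SE, n = 3 mice per group), Trpm6, a magnesium channel, 0.57 ± 0.12, and the calcium pump gene Atp2b1 0.37 ± 0.11. Cldn2 (-0.47 ± 0.15) and the zinc exporter gene Slc30a1 (-0.22 ± 0.09) were lower, and the vitamin D receptor gene Vdr (0.06 ± 0.07) and the calcium channel gene Trpv6 (-0.07 ± 0.36) stayed near 0. The median of the group was 0.225, and 1 other split of the 6 mice into 3 and 3 gave a larger one (0.239), although the score of the group was higher in every stressed mouse (0.065 to 0.216) than in every resting mouse (-0.309 to -0.043). Markers of small intestine and Paneth cells were higher too (7 of 9), and Sis, at 79.6, 34.6 and 56.3 CPM in stressed mice 10, 11 and 13, ranked these mice as Slc11a2 did (78.0, 49.1 and 64.1 CPM), so the stretch of gut or the tissue content was not told apart from stress for this group. The defensin genes of that list had too few counts to test, and an order of 3 mice can match by chance.

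Of 15 fatty acid synthesis genes other than Me1, 14 were higher, with a median of 0.187. Another split of the 6 mice gave a median almost as large (0.17). Of the 15, 6 had an unadjusted edgeR p under 0.05, all higher, and none passed over all genes. Acaca (0.11), Acly (0.09), Acss2 (0.04) and Elovl6 (0.03) stayed near 0. Thrsp had a log2 fold change of 1.32 ± 0.27, Scd1 1.03 ± 0.17, Fasn 0.38 ± 0.09 and Srebf2, the sterol regulator, 0.29 ± 0.07. Thrsp, Scd1 and Fasn are also abundant in fat, and adipocyte markers were higher too (13 of 15, median 0.29), so a share from attached fat was not told apart for this group. The Hoxa genes were lower in 10 of 10 cases (median -0.81), whereas 8 of 8 Hoxb genes were higher (median 0.19) and Hoxd genes went both ways. Resting mouse 19 had Hoxa levels like the stressed mice: Hoxa13 was at 15.5, 11.6 and 1.82 CPM in resting mice 15, 17 and 19, and at 2.26, 1.80 and 0.608 CPM in stressed mice 10, 11 and 13. Another split of the 6 mice gave a larger Hoxa median (0.99).

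The 5 changed genes were more than any other split of the mice gave (1 at most), as were the 4 higher (1 at most), the real split being 1 of 10 in both cases, but 4 of the 10 splits gave at least 1 gene in one direction, as many as the 1 lower gene. 3 mice against 3 make too few splits for a share under 0.05. By genes with an unadjusted edgeR p under 0.05 the real split did not rank highest. It gave 1116, and the split of mice 15, 17 and 11 against the others gave 1187. For the lists, 7 of the 10 splits gave at least the 11 of the real split, and the highest other gave 12, so the count of lists with a preset correlation does not set the real groups apart. With the Hoxa score in the fit the 5 genes kept a median share of 0.971 of their log2 fold change. Of the 5, 1 stayed past the threshold, while their median SE went from 0.165 to 0.189 with 1 degree of freedom fewer. S100g went from 1.78 ± 0.17 to 1.47 ± 0.22 and Gm26917 from -2.07 to -1.47, but Igkv6-14 from 4.10 to 5.45. H2-Q1 (0.617) and Me1 (0.573) moved little. A difference between mice that the Hoxa genes track, such as the stretch of colon taken, therefore cannot be told apart from stress for these genes, since the score itself differs between the groups. Within the groups the score and the mean of the 5 genes showed no relation (exact permutation p = 0.806). That mean pools genes whose changes shrank and grew with the score in the fit, so it cannot decide the question for single genes. For Gm26917, carry-over of RNA without a poly(A) tail may play a part and stays open: 7 of 10 tested snRNA, scaRNA and misc_RNA genes were lower, with a median of -0.309 (SD 0.782) against -2.07, but at a median of 0.781 CPM they lie too low to judge by. These genes are also not ribosomal RNA genes, so they do not measure carry-over of ribosomal RNA itself. Gm42418, from the same ribosomal RNA region, was at 746, 803 and 950 CPM in resting mice 15, 17 and 19 and at 460, 558 and 1050 CPM in stressed mice 10, 11 and 13.

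The shift of the cholesterol synthesis list (mean 0.33) was larger than in any other split of the mice (highest 0.251; 1 of 10), which are too few to judge chance. RNA from attached fat, as far as the adipocyte score tracks it, was argued against. With that score in the fit the median of the list was 0.378, against 0.32 without it, and 11 members passed over the list alone. The adipocyte score overlaps between the groups. Stressed mouse 13, with the highest cholesterol synthesis score (0.343), was at -0.103, below resting mouse 17 (-0.033). How far the result rests on that mouse was not tested. A difference that the Hoxa genes track may account for part of it and stays open, since with the Hoxa score the median was 0.128 and the median SE of the members went from 0.0952 to 0.129. Within the groups the relation of the 2 scores had an exact permutation p = 0.139 (2-sided, the smallest possible being 0.0278; 0.278 adjusted over 2 relations), and the 5 distal colon markers other than Hoxa13 had a median of 0.05 (SD 0.32). Feeding and time of day, which restraint can shift, were not tested.

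Mesothelial transcripts, from the outer lining of the gut, were higher in 10 of 10 cases with a median log2 fold change of 1.18. None passed over all genes, and the highest median of another split of the mice was 0.724. Upk3b was at 6.74 ± 1.53 against 2.49 ± 0.94 CPM and Msln at 5.08 ± 1.08 against 2.12 ± 0.821 CPM (SD, n = 3 each). For the genes chosen, more outer muscular wall as the whole source was argued against, but weakly. The largest median among smooth muscle, enteric neuron, glia and interstitial cell lists was 0.176. It lay below the mesothelial median by more than the SD of the mesothelial genes (0.467). Both that median and that SD come from genes chosen after seeing the data, whereas the wall lists were fixed before. Such a choice can raise the median, so the comparison cannot exclude this source. A smaller share from the wall stays open, since smooth muscle (17 of 20) and enteric neuron markers (19 of 22) were mostly higher too. Attached mesentery with its fat and vessels may be a source, with adipocyte and haemoglobin transcripts also higher, but the endothelial list had a median of -0.0733 and is abundant in the colon itself, and the adipocyte score overlaps between the groups: stressed mouse 13, with the highest mesothelial score (0.764), is at -0.103, below resting mouse 17 (-0.033). This stays open beside an effect of stress.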
